A study of Caenorhabditis elegans with 18 samples.

How the data were processed

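RNA sequencing measured transcript levels in whole wild-type N2 Caenorhabditis elegans, the standard laboratory strain, grown with or without ascr#10, an ascaroside pheromone made mainly by males. Per the labels' protocols, worms synchronised as starved first-stage larvae were placed at 30 to 50 per plate, on plates treated with ascr#10 or with water, and grown at 20 degrees C. The ascr#10 stock was kept in ethanol and diluted in water to give 2.2 or 1.1 fg per plate, by plate size, while control plates received water. Males and delayed worms were taken off before harvest. RNA was column-purified with DNase treatment, and directional single-end libraries were made with a kit that marks strand. There were 18 samples in 6 groups of 3. Water and ascr#10 worms were sampled at 50 h and 58 h after synchronisation, and the 58 h worms were collected and sequenced again because of insufficient depth. The 12 samples of the first collection hold both ages, and the 6 of the second collection hold 58 h alone. Collection is therefore a batch at 58 h, of newly collected worms as well as new sequencing. One characteristic in the labels gives 58 h for every sample. The titles and descriptions give 50 h for 6 of them, and these were used together with the design text. The labels call the samples of a condition independent, and p-values measure the spread between these samples.

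The deposited estimated counts per gene come from salmon, per the file headers and names, summed over transcripts and not normalized. The aligner settings, genome build, annotation, salmon version and strand setting are not given in the sources used here. Of their values, 95.2% are whole numbers, and all were rounded to whole numbers before testing. Per the file headers, the deposited length-scaled estimated counts were also used, as an alternative, and so were the deposited TPM values (transcript abundance scaled for length and depth). Tables at transcript level and a table of otherwise scaled counts were not used. Gene identifiers and symbols are those of the tables. Coordinates come from the Ensembl release 115 annotation of the WBcel235 genome by identifier, which held 46167 of the 46253 identifiers and 15987 of the 16006 genes tested. Strand use in counting is not stated, so overlapping antisense genes may not be told apart. Many msp genes and some vit genes are near-identical copies, and some col genes may be alike. Reads may have been split among such copies, so single members of these are uncertain.

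Total counts per sample, in units of 1e6 counts (M), were 25.6 M to 32.9 M in the first collection and 54.3 M to 72.3 M in the second. Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 16006 genes. Library sizes were scaled by TMM. Differences were tested with edgeR 4.0.16 quasi-likelihood F tests with robust dispersion in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 18 samples shared one estimate of the spread. The exposure effects at 50 h and 58 h were fitted with one intercept for each age and collection, so that the 58 h effect is within collection and common to both. Age effects and differences between effects came from a model of 6 group means, with age compared within the first collection. The biological coefficient of variation was 3.57% in the former model and 2.86% in the latter. The former takes 1 effect for both collections, so differences between them at 58 h enter its spread, also for tests at 50 h. For vit-3 at 50 h the SE was 0.054 in the former and 0.024 in the latter. Levels are CPM, counts scaled to the TMM-adjusted library size, with the SD over 3 samples. Fold changes are given as log2 with their standard error (SE).

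Before the data were examined, 29 gene lists were fixed. The germline lists were oocyte and maternal transcripts, germline progenitor and meiotic entry, meiotic chromosome genes, germ granule and small RNA genes, DNA replication and mitosis, apoptosis and engulfment, major sperm proteins, and other spermatogenic genes. Lists of other cell types were zygotic embryonic genes, male-specific somatic genes, pan-neuronal genes, muscle, intestine, and somatic gonad. Signalling lists were serotonin signalling, FMRFamide-like neuropeptides, neuropeptide-like proteins, insulin-like peptides, and the insulin and TGF-beta pathway. The rest were vitellogenins, cuticle collagens, moulting genes, heat shock and chaperones, oxidative stress and detoxification, innate immunity, fatty acid metabolism, ascaroside biosynthesis, cytosolic ribosomal proteins, and the mitochondrial respiratory chain. 3 intended members were not found by symbol. Each list was tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. Genes are named by a rule fixed at the same time. It takes up to 8 genes in each direction with the largest change among called genes averaging at least 4 CPM, up to 4 members of each list with the smallest p, and a fixed set of serotonin, ascaroside, yolk and germline genes. Of these, the text gives those that describe a group.

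Alternatives fixed at that time were DESeq2 1.42.0, size factors of the RLE kind, no low-count filter and one at 50 counts, length-scaled counts, limma on log2(TPM + 1), fits on part of the samples, each collection alone, no batch term, the replicate number as a block, and each sample left out. Counts of genes changed at least 1.5-fold were added after the data were seen. All 18 pairs of samples within groups differed by more than counting noise (chi-square per gene from 1.66 to 19.2), so no pair was merged as repeat deposits of one library. Repeat libraries of one sample would also differ by more than that, so separate samples rest on the labels. The tests were tried on simulated data with 200 changed genes. For changes of 1.2-fold, 1.5-fold and 2-fold, calls recovered 48.5%, 82.5% and 90.1% at 50 h and 50.0%, 76.8% and 93.1% at 58 h. They recovered 61.3%, 75.4% and 90.6% for age. For the effect at 58 h minus that at 50 h they recovered 31.2%, 56.3% and 69.8%, and for the second minus the first collection 23.6%, 55.4% and 75.8%. Unchanged genes made up 4.61% to 8.23% of calls. With 200 changed genes, these simulations did not hold the differences between collections seen in the data, where the 58 h effect differed for 1783 genes. Such differences enter the spread of the model used for exposure at 50 h and 58 h. The recovery given for these tests may therefore be higher than that in the data.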

Results

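The data are transcript counts from whole C. elegans worms, with males removed, exposed to ascr#10 or to water from the first larval stage. The series is presented under a title about a male pheromone and the quality of the oogenic germline, the egg-producing tissue. At 50 h there were 3 water and 3 ascr#10 samples. At 58 h there were 6 of each, as 3 from the first collection and 3 from the second. Total counts ran from 25.6 M to 32.9 M per sample in the first collection and from 54.3 M to 72.3 M in the second, over 46253 genes. One ascr#10 sample of 50 h, replicate 2, had 2.25% of its counts in ribosomal RNA genes, against 0.347% to 0.982% in the other 17 samples.

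Age set the samples apart most. The first principal component of log2 CPM held 84.6% of the variance and placed the water samples of 50 h at a mean of -145 ± 0.50 and those of 58 h at 56.1 ± 0.35 and 65.2 ± 0.12 in the first and second collections (SD, n = 3 each). The ascr#10 samples lay further in the direction of age in every set. Their means were -136 ± 0.59 at 50 h and 79.6 ± 0.95 and 80.4 ± 0.92 at 58 h. The second component, with 6.41% of the variance, separated the 2 collections of 58 h.

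**Figure D1:**
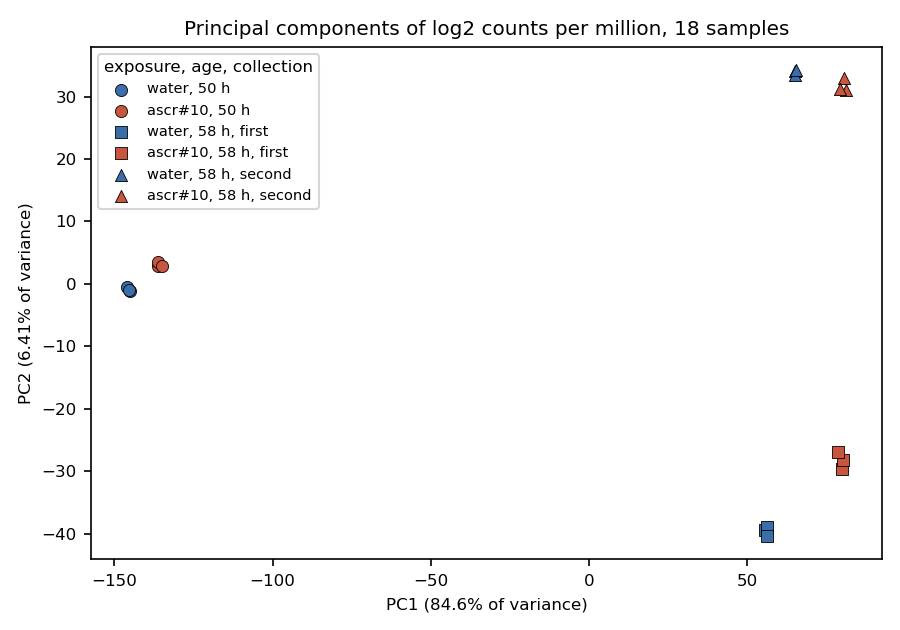
Principal components of log2 CPM for the 18 samples, with PC1 (84.6% of variance) on the x axis and PC2 (6.41%) on the y axis. Colour gives exposure and shape gives age and collection. The ascr#10 samples of each set lie at higher PC1 than their water controls, for example 79.6 against 56.1 in the first collection of 58 h.

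The comparison at 50 h asks what ascr#10 changed in the younger worms. Among the genes that rose in exposed worms were fat-7, elo-5, elo-6 and hacd-1, of fatty acid metabolism, and the yolk gene vit-3. fat-7 (WBGene00001399, chromosome V from 7151353 to 7153146), a stearoyl-CoA desaturase, rose 1.72-fold from 54.8 ± 0.756 to 94.4 ± 3.02 CPM (SD, n = 3 each). The elongases elo-5 and elo-6 rose by log2 0.65 and 0.60, and hacd-1, a hydroxyacyl-CoA dehydrogenase, by 0.73. vit-3 (WBGene00006927, chromosome X from 3567355 to 3572549), which encodes the yolk protein vitellogenin, rose from 1569 ± 11.1 to 2362 ± 8.77 CPM, a log2 fold change of 0.59 ± 0.054 (SE, edgeR adjusted p = 4.9e-06).

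Of the 6 vitellogenins, 4 rose when adjusted over all genes and 6 when adjusted over the list alone. The list had a median log2 fold change of 0.47 (camera adjusted p = 1.76e-09, and adjusted p = 0.141 with an estimated correlation). vit-1 and vit-4 rose by 0.59 and 0.58 and vit-5 by 0.36, while vit-2 was at 0.12 (adjusted p = 0.096 over all genes). Reads may be shared among vit copies, so single members are uncertain. Of 24 fatty acid metabolism genes, 7 rose and 2 fell, and 9 and 2 when adjusted over the list alone (camera adjusted p = 1.77e-05, and adjusted p = 0.173 with an estimated correlation).

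Heat shock and chaperone genes rose as a list. Of 20, 10 rose and 0 fell, with 11 when adjusted over the list alone, and the list passed with the preset (camera adjusted p = 2.03e-08) and with an estimated correlation (adjusted p = 0.0123). The small heat shock gene hsp-16.48 rose 1.71-fold, from 13.8 ± 0.823 to 23.6 ± 0.505 CPM, and the abundant chaperone hsp-90 by 1.07-fold. gst-4, a glutathione S-transferase of the oxidative stress list, rose 1.78-fold, but of that list 2 rose and 3 fell (4 and 3 over the list alone) and it was not called (adjusted p = 0.888). gcsh-1, of the glycine cleavage system, had a log2 fold change of 1.34 ± 0.30 and T22B7.7 one of 1.04 ± 0.12.

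Smaller shifts ran through abundant genes. Of 27 respiratory chain genes 11 rose (18 over the list alone), with a median of 0.08, and the call held with an estimated correlation (camera adjusted p = 2.81e-10 and 0.000124). cox-6C and atp-5 rose by 0.16 and 0.12. Of 78 cytosolic ribosomal protein genes 26 rose (57 over the list alone), with a median of 0.08 (camera adjusted p = 6.94e-18, and adjusted p = 0.141 with an estimated correlation), among them rpl-27 and rpl-15. Of 26 oocyte and maternal transcripts 5 rose (9 over the list alone), with a median of 0.07 (adjusted p = 5.54e-06, and adjusted p = 0.466 with an estimated correlation). perm-2, an eggshell gene, rose by 0.22 and oma-2, which acts in oocyte maturation, by 0.13. Genes of like length and expression rose by similar amounts. Random lists matched on both had medians of 0.051 to 0.099 for the respiratory chain, 0.084 to 0.115 for ribosomal proteins and 0.037 to 0.079 for oocyte transcripts (central 95% of 10000 lists), against up to 0.070 for chaperones and 0.080 for vitellogenins. Matching on expression was poor for vitellogenins, with a median log2 CPM of 12.5 in the list and 9.45 in matched lists. It was imperfect for ribosomal proteins (10.1 and 8.94). On log2(TPM + 1) the medians of the respiratory chain, ribosomal protein and oocyte lists were 0.008, 0.006 and 0.003, those of the chaperone and fatty acid lists 0.073 and 0.002, against 0.147 and 0.073 with TMM, and that of all genes -0.059.

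Genes with less transcript at 50 h included scl-2 (WBGene00009895, chromosome IV from 13057710 to 13059062), a secreted SCP-family protein, which fell from 48.9 ± 0.465 to 27.2 ± 0.840 CPM. The cytochrome P450 genes cyp-37B1 and cyp-32B1 had log2 fold changes of -0.80 ± 0.14 and -0.72 ± 0.14. Of 32 other spermatogenic genes 5 fell (6 over the list alone) with a median of -0.12 (camera adjusted p = 0.0239, and adjusted p = 0.466 with an estimated correlation), among them spe-9 and fer-1, which act in sperm function. Of 33 msp genes, which encode the major sperm proteins, 1 fell and 0 rose (1 over the list alone, adjusted p = 0.696). Cuticle collagens moved both ways, with 21 of 122 higher and 38 lower (25 and 53 over the list alone), and the list was not called (adjusted p = 0.929). Set against random lists matched on length and expression, the collagen median of -0.184 lay below (-0.033 to 0.039), as did that of msp genes (-0.022 against 0.029 to 0.106) and of other spermatogenic genes (-0.074 to 0.057), and that of insulin-like peptides, 0.225, lay above (-0.174 to 0.078). col-143 rose by 0.54, and col-156 had a log2 fold change of -0.67.

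Genes of ascaroside side-chain synthesis also moved both ways. The acyl-CoA oxidase genes acox-1.2 and acox-1.3 rose by 0.78 and 0.35, while acox-1.6 and acox-3 had log2 fold changes of -0.44 and -0.54 and daf-22, the thiolase of the pathway, -0.18 (adjusted p = 0.026). Of this list of 10, 2 rose and 3 fell (3 and 3 over the list alone), and it was not called (adjusted p = 0.831). bas-1, a decarboxylase used in serotonin and dopamine synthesis, rose by 0.45, the 1 called gene of 11 in serotonin signalling (2 over the list alone, adjusted p = 0.559). tph-1, mod-1 and mod-5, for serotonin synthesis, a receptor and reuptake, were at -0.05, -0.14 and -0.02 (adjusted p = 0.96, 0.71 and 0.96). The cell corpse engulfment receptor ced-1 had a log2 fold change of -0.16 and ced-8 one of -0.79 at a level of 0.803 CPM in ascr#10. The caspase gene ced-3 was at 0.02, the Notch receptor gene glp-1 at -0.05 and the yolk receptor gene rme-2 at 0.08, and none of the last 3 passed (adjusted p = 0.76, 0.30 and 0.059).

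The other lists were not called at 50 h. DNA replication and mitosis was nearest, with 1 of 25 higher (0 over the list alone, adjusted p = 0.0568). Apoptosis and engulfment had 2 of 16 lower, moulting genes 1 of 29 higher and 4 lower, intestine 2 of 18 higher and 2 lower, neuropeptide-like proteins 3 of 69 higher and 1 lower, and insulin-like peptides 1 of 24 higher and 1 lower (daf-28 and ins-7). Somatic gonad had 1 of 13 higher and 1 lower, innate immunity 1 of 20 lower, germline progenitor genes 1 of 14 lower and germ granule genes 1 of 20 higher. Meiotic chromosome genes (25), zygotic embryonic genes (19), male-specific somatic genes (4), pan-neuronal genes (19), FMRFamide-like neuropeptides (30), the insulin and TGF-beta pathway (19) and muscle (21) had 0 called members. Over each list alone these counts were 2 lower for apoptosis, 1 and 5 for moulting, 4 and 2 for intestine, 3 and 1 for neuropeptide-like proteins, 1 and 2 for insulin-like peptides, 0 for innate immunity, and as over all genes for the rest. Median, mean and test differed in sign in the apoptosis, serotonin, FMRFamide-like, male-specific, insulin and TGF-beta, oxidative stress, ascaroside and germline progenitor lists.

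In all, 1306 of 16006 genes passed at 50 h (edgeR quasi-likelihood, adjusted p under 0.05), 761 higher and 545 lower, and of these 59 rose and 88 fell by at least 1.5-fold. The split moved to 538 higher and 716 lower with the stricter count filter, and to 293 and 1695 with limma on log2(TPM + 1). Leaving out any 1 of the 6 samples gave 741 to 862 genes, 772 without the sample rich in ribosomal RNA, and a fit on the 6 samples alone gave 2840. The joint fit takes its spread in part from differences between the collections of 58 h, so a missing call at 50 h may reflect them.

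The comparison at 58 h asks the same of older worms, in both collections. Exposed worms had less transcript of sperm genes. msp-76 (WBGene00003463, chromosome IV from 9689015 to 9689398) fell from 15.3 ± 0.271 to 9.19 ± 0.721 CPM in the first collection and from 18.2 ± 0.615 to 13.1 ± 0.565 in the second (SD, n = 3 each). ssq-4 (WBGene00006053, chromosome IV from 5016479 to 5017766), a sperm-specific gene, had a log2 fold change of -0.54 ± 0.030 (SE, edgeR adjusted p = 1.2e-15). Cuticle collagens fell as well, 35 of 122 with a list median of -0.19 (camera adjusted p = 1.44e-06 and, with an estimated correlation, 0.0103).

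Of 33 msp genes, 25 fell and 0 rose (26 over the list alone), with a median of -0.51 over both collections, -0.59 in the first and -0.45 in the second. Of 32 other spermatogenic genes, 22 fell and 0 rose (24 over the list alone), with a median of -0.47, and -0.58 and -0.38 within collections. Both lists passed with the preset (camera adjusted p = 7.61e-23 and 6.2e-16) and with an estimated correlation (6.01e-05 and 0.0019). msp-81 and msp-36 had log2 fold changes of -0.61 and -0.49, ssq-1 one of -0.56, the sperm phosphatase gene gsp-3 one of -0.60 (-0.82 and -0.48 within collections) and ssp-11 one of -1.06 ± 0.23 (-0.52, adjusted p = 0.468, and -1.39). Single msp genes are uncertain, since the copies share sequence.

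Of the 122 collagens 1 rose, and over the list alone 37 fell and 1 rose. Within collections the medians were -0.26 and -0.08 (camera adjusted p = 3.03e-08 and 0.00324, and with an estimated correlation adjusted p = 0.00812 and 0.0866). On log2(TPM + 1) the collagen median was -0.094 and that of the spermatogenic genes other than msp -0.302. col-146 had a log2 fold change of -1.07 ± 0.14, with -1.26 in the first collection and -0.21 in the second (adjusted p = 0.406), col-133 one of -0.66 (-0.82 and -0.46) and col-139 one of -0.29. The transporter genes pgp-5 and pgp-6 fell to 0.594 and 0.577 of the water level, with log2 fold changes of -0.42 and -0.54 in the first collection and -0.91 and -0.89 in the second. Among higher genes, clec-265 and pho-9 both rose 1.19-fold, by log2 0.46 and 0.45 in the first collection and, without passing, 0.15 and 0.08 in the second (adjusted p = 0.078 and 0.23).

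Of 21 muscle genes 15 fell (17 over the list alone), with a median of -0.13 (camera adjusted p = 4.82e-08, and adjusted p = 0.296 with an estimated correlation). The collections differed. In the first, 1 was higher and 2 lower with a median of 0.01 (adjusted p = 0.929), and in the second 21 of 21 were lower with a median of -0.27 (adjusted p = 1.83e-22). unc-54 (WBGene00006789, chromosome I from 14855901 to 14863482), the body wall myosin, had log2 fold changes of -0.10 and -0.30 in the 2 collections, myo-3 -0.10 and -0.37, and the troponin gene tni-4 -0.07 (adjusted p = 0.37) and -0.48. Among neuropeptide genes, 7 of 30 FMRFamide-like genes (7 over the list alone, adjusted p = 0.00406) and 10 of 69 neuropeptide-like genes (7 over the list alone, adjusted p = 0.00814) were lower in the joint fit, and 0 were higher. With an estimated correlation both had adjusted p = 0.273, and neither was called in the first collection (adjusted p = 0.91 and 0.803). The median of the neuropeptide-like list, -0.111, lay within that of matched random lists (-0.143 to -0.016), and that of the FMRFamide-like list, -0.143, just below (-0.137 to 0.012). flp-1 had log2 fold changes of -0.08 (adjusted p = 0.64) and -0.68 in the 2 collections, flp-18 -0.14 (adjusted p = 0.314) and -0.22, and nlp-14 -0.06 (adjusted p = 0.769) and -0.52.

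Of 26 oocyte and maternal transcripts 21 rose and 0 fell (24 over the list alone), with a median of 0.09, and 0.03 and 0.13 within collections (camera adjusted p = 3.11e-10, and adjusted p = 0.172 with an estimated correlation). puf-11 and spn-4, which regulate maternal mRNA, rose by 0.12 and 0.09, and egg-3 and egg-1, of the egg surface, by 0.11 and 0.10. In the first collection these 4 were at 0.06, 0.04, 0.07 and 0.05 and did not pass (adjusted p = 0.127, 0.272, 0.0743 and 0.168), and in the second they rose by 0.19, 0.14, 0.15 and 0.15. Of 25 DNA replication and mitosis genes 19 rose (21 over the list alone, median 0.07, adjusted p = 1.49e-10, and adjusted p = 0.162 with an estimated correlation). pcn-1 (WBGene00003955, chromosome IV from 4047937 to 4049448), which encodes the replication clamp PCNA, rose from 437.7 ± 8.03 to 459.2 ± 8.15 CPM in the first collection and from 391.1 ± 7.87 to 435.4 ± 9.15 in the second. cdk-1 rose by 0.10, and mcm-6 by 0.09, with 0.05 in the first collection (adjusted p = 0.182) and 0.13 in the second.

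Smaller numbers rose among germ granule genes (9 of 20, 11 over the list alone, with csr-1 and pgl-3), meiotic chromosome genes (6 of 25, 6 alone, with rad-51 and cosa-1) and germline progenitor genes (6 of 14, 6 alone, with lag-1 and lst-1). These lists were called with the preset (adjusted p = 6.79e-06, 0.000795 and 0.0142), and with an estimated correlation their values were adjusted p = 0.256, 0.273 and 0.338. Within the first collection these 3 were not called (adjusted p = 0.116, 0.848 and 0.796), and in the second they were. The 6 genes named passed in the second and not in the first, where csr-1 was at 0.02 (adjusted p = 0.708) and lag-1 at 0.09 (adjusted p = 0.0932). Random lists matched on length and expression reached 0.067 for oocyte, 0.064 for replication, 0.060 for progenitor, 0.059 for germ granule and 0.057 for meiotic genes, against list medians of 0.085, 0.070, 0.075, 0.057 and 0.048. On log2(TPM + 1) these medians were 0.049, 0.037, 0.044, 0.022 and 0.014, with -0.021 over all genes.

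Of 78 ribosomal protein genes 36 rose and 1 fell (57 and 2 over the list alone), with a median of 0.05 (camera adjusted p = 1.32e-13, and adjusted p = 0.172 with an estimated correlation), among them rpl-36 and rpl-12. The median was 0.022 on log2(TPM + 1). Respiratory chain genes had 3 of 27 higher and 2 lower (3 and 2 alone, adjusted p = 0.0177, and adjusted p = 0.0773 with an estimated correlation). Their median of 0.02 turned to -0.01 on log2(TPM + 1), where the median of all genes was lower still. With TMM it lay below matched lists (0.024 to 0.073). Chaperones had 7 of 20 higher and 3 lower (8 and 5 alone, adjusted p = 0.0223, and adjusted p = 0.256 with an estimated correlation), with a median of 0.03 and a mean of -0.07. hsp-60 rose by 0.11, and hsp-1 by 0.10, with 0.06 in the first collection (adjusted p = 0.0937) and 0.15 in the second, while hsp-16.2 had log2 fold changes of 0.20 (adjusted p = 0.44) and -0.46 in the 2 collections.

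Lists not called at 58 h held called members too. Fatty acid metabolism had 1 of 24 higher and 7 lower (adjusted p = 0.249), with acs-2, an acyl-CoA synthetase, at -0.47 over both collections, -0.67 in the first and -0.24 in the second, and fat-2 at -0.11, -0.03 (adjusted p = 0.519) and -0.19, and vitellogenins had 0 of 6 (adjusted p = 0.315). Within collections the vitellogenins went opposite ways. In the first, 3 of 6 rose (3 over the list alone, median 0.07, adjusted p = 0.0204, and adjusted p = 0.501 with an estimated correlation), and in the second 6 of 6 fell (6 over the list alone, median -0.16, adjusted p = 0.00017, and adjusted p = 0.152 with an estimated correlation). Ascaroside biosynthesis had 1 of 10 higher and 3 lower (1 and 5 alone, adjusted p = 0.168), with acox-3 at -0.32 over both collections, -0.10 in the first (adjusted p = 0.40) and -0.47 in the second. The insulin pathway had 1 of 19 higher and 3 lower, with the kinase gene akt-2 at -0.24 over both collections, -0.10 in the first (adjusted p = 0.416) and -0.36 in the second. Apoptosis and engulfment had 4 of 16 higher and 1 lower (adjusted p = 0.0759), with ced-10 at 0.10 and ced-1 at -0.10. Innate immunity had 4 of 20 lower (adjusted p = 0.0547), pan-neuronal genes 6 of 19 lower, intestine 4 of 18 lower and 1 higher, oxidative stress 5 of 20 lower and 2 higher, somatic gonad 3 of 13 lower, moulting 2 of 29 lower and 1 higher, insulin-like peptides 2 of 24 lower and zygotic embryonic genes 1 of 19 lower. Serotonin signalling (11) and male-specific somatic genes (4) had 0. Over each list alone, intestine had 6 lower and 2 higher, pan-neuronal genes 1 higher besides the 6, zygotic genes 0, and the other lists without such a count had the same numbers as over all genes. Median, mean and test differed in sign in the chaperone, insulin and TGF-beta, moulting and oxidative stress lists.

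tph-1, at 0.290 to 0.433 CPM on average, had a log2 fold change of -0.58 ± 0.25 that did not pass (adjusted p = 0.089). mod-1 was at -0.24, mod-5 at 0.09, daf-22 at -0.07, vit-2 at -0.08 and glp-1 at 0.04, none of which passed (adjusted p = 0.15, 0.64, 0.16, 0.069 and 0.12). Within the second collection daf-22 and vit-2 passed, at -0.17 and -0.15, and in the first they were at 0.06 and 0.00 (adjusted p = 0.532 and 0.985). rme-2 rose by 0.06 (adjusted p = 0.011) and ced-3 by 0.08 (adjusted p = 0.0041), and in the first collection they were at 0.04 and 0.03 (adjusted p = 0.311 and 0.532). The cell death gene ced-13 had 0 to 3 counts per sample and was not tested.

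In all, 3548 of 16006 genes passed at 58 h, 1494 higher and 2054 lower, and of these 13 rose and 467 fell by at least 1.5-fold. The split turned to 2538 higher and 1885 lower with size factors of the RLE kind and to 2715 and 1885 with DESeq2, and the number was 394 without a batch term. It was 1771 and 1500 on the samples of 58 h alone, and 161 and 1675 with limma on log2(TPM + 1).

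**Figure D2:**
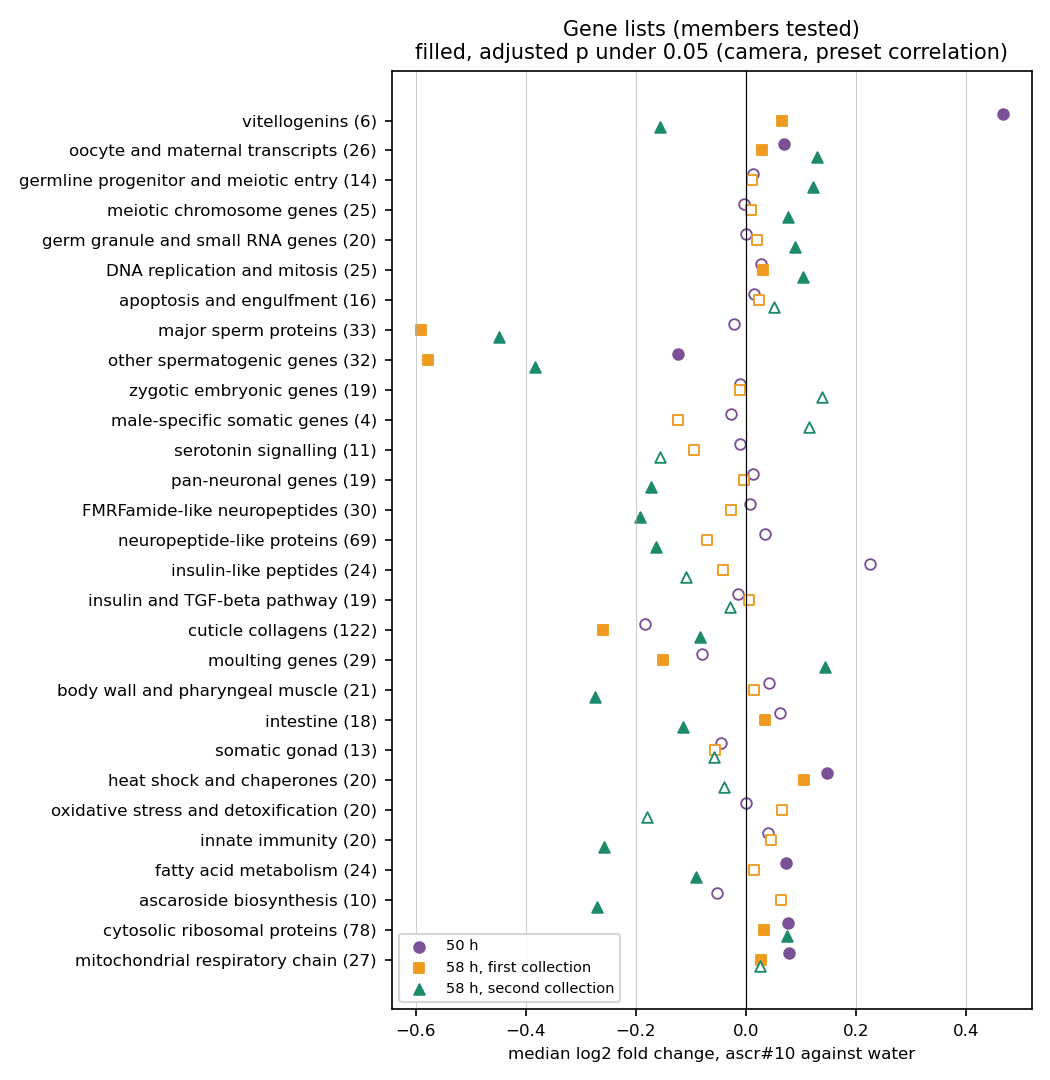
Median log2 fold change (x axis) of ascr#10 against water in each of the 29 gene lists (y axis, number of genes tested in parentheses), for 50 h, the first collection of 58 h and the second. Filled symbols passed camera with the preset correlation at an adjusted p under 0.05. Sperm lists lie lowest at 58 h in both collections (-0.59 and -0.45 for msp genes), and the muscle list lies at 0.01 in the first and -0.27 in the second.

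**Figure D3:**
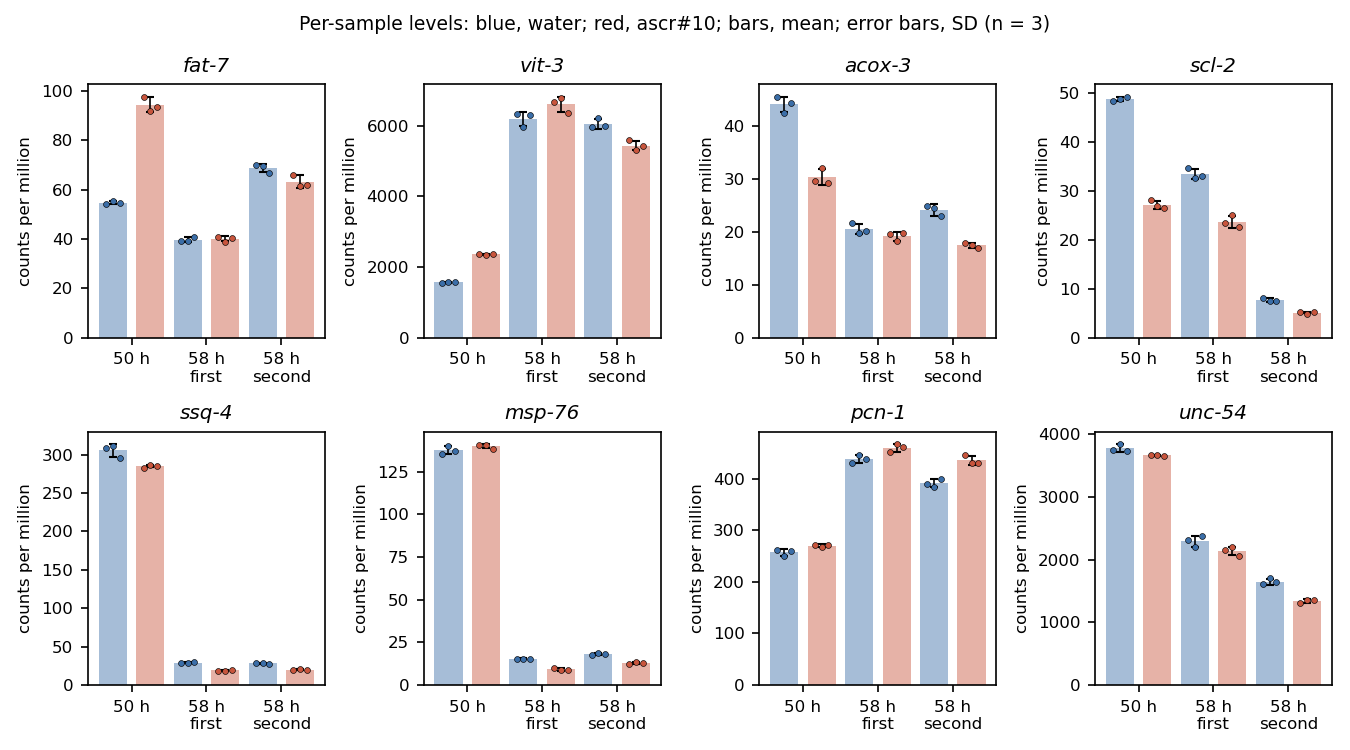
Levels in CPM (y axis) of 8 genes in each of the 18 samples, by age and collection (x axis). Points are samples, bars are means and error bars the SD over 3 samples, with water in blue and ascr#10 in red. fat-7 at 50 h goes from 54.8 in water to 94.4 in ascr#10, while at 58 h its means are 39.8 and 40.0 in the first collection.

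The comparison of 58 h with 50 h asks what changed as water worms aged, within the first collection. Cuticle and sperm transcripts fell, and oocyte and embryonic transcripts rose. sdz-30 (WBGene00011432, chromosome I from 13307051 to 13308685), vet-6 and pes-10, expressed in early embryos, rose by log2 9.17 ± 0.22, 7.58 ± 0.12 and 7.06 ± 0.23 (SE, first collection, n = 3 each). vit-3 rose 3.95-fold, from 1569 ± 11.1 to 6194 ± 204 CPM, and vit-2 1.72-fold. col-138 (WBGene00000711, chromosome IV from 17182884 to 17183729) fell from 168.8 ± 0.65 to 0.601 ± 0.0655 CPM, and the cuticle genes bli-2, rol-1 and sqt-1 had log2 fold changes of -8.44, -8.33 and -8.57. msp-56 and ssq-4 fell to 0.0959 and 0.0957 of their level at 50 h.

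By list, 26 of 26 oocyte genes (median 0.70, camera adjusted p = 7.86e-12) and 25 of 25 replication genes (median 0.69, adjusted p = 1.84e-11) rose, as did 18 of 19 zygotic embryonic genes (median 2.14, adjusted p = 1.15e-05). oma-2 and rme-2, of the oocyte list, rose by 0.88 and 0.73, and the cyclin gene cyb-3 and the ribonucleotide reductase gene rnr-2, of the replication and mitosis list, by 1.12 and 1.10. Of 33 msp genes 32 fell (median -3.33, adjusted p = 5.59e-12), and of 32 other spermatogenic genes 31 fell (median -3.23, adjusted p = 5.8e-11), gsp-4 to 0.0909 of its level at 50 h. Of 122 collagens 101 fell and 15 rose (median -3.93, adjusted p = 1.06e-12), and of 29 moulting genes 21 fell and 6 rose (adjusted p = 0.00258). Of 10 ascaroside biosynthesis genes 8 fell (adjusted p = 0.0055), with daf-22 at -0.83 and acox-1.6 at -1.56. Meiotic chromosome genes (21 of 25 higher and 2 lower, with him-17, adjusted p = 0.00147), apoptosis genes (15 of 16 higher, with ced-9 and ced-3, adjusted p = 4.9e-05) and chaperones (15 of 20 higher and 3 lower, adjusted p = 0.00585) were called too. These 11 lists also passed with an estimated correlation, and over each list alone the counts were the same apart from 16 collagens higher. On log2(TPM + 1) the medians of the zygotic and collagen lists were 1.13 and -2.50, and the median of all genes moved from -0.10 to -0.01.

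Called with the preset alone were vitellogenins (6 of 6 higher, adjusted p = 0.159 with an estimated correlation), germline progenitor genes (11 of 14 higher, 3 lower, adjusted p = 0.237, with glp-1 and lst-1) and germ granule genes (15 of 20 higher, 2 lower, adjusted p = 0.195, with meg-1 and meg-3). So were muscle (21 of 21 lower, adjusted p = 0.0755, with myo-3 and mup-2), intestine (13 of 18 lower, 4 higher, adjusted p = 0.194, with pept-1 and ifb-2), ribosomal proteins (77 of 78 lower, median -0.21, adjusted p = 0.122, with rps-27), FMRFamide-like genes (26 of 30 lower, adjusted p = 0.107, with flp-10) and neuropeptide-like genes (40 of 69 lower, 4 higher, adjusted p = 0.119, with nlp-24). Innate immunity (15 of 20 lower, 3 higher, adjusted p = 0.107) and fatty acid metabolism (19 of 24 lower, 4 higher, adjusted p = 0.122) complete these, each p here being that with an estimated correlation. With the preset, camera gave adjusted p from 3.39e-08 to 0.0196 for these lists, apart from 4.56e-09 for ribosomal proteins. Over the list alone, 27 FMRFamide-like and 38 neuropeptide-like genes were lower, and the other counts were the same. Not called were pan-neuronal, serotonin, insulin-like, insulin and TGF-beta, somatic gonad, male-specific, oxidative stress and respiratory chain genes (adjusted p from 0.0654 to 0.868). tph-1 was at -0.47 (adjusted p = 0.25), mod-1 at -0.13 (0.51) and mod-5 fell by 0.65.

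Of 16006 genes, 12789 passed between 50 h and 58 h in water, 6006 higher and 6783 lower, and 12946 in ascr#10, 5919 higher and 7027 lower. The age effects in the 2 exposures share no library and had a Pearson r of 0.938 across genes, which are not independent replicates. Of 11858 genes called in both, 99.6% had the same sign. In each, 21 of 29 lists were called, 9 higher and 12 lower. Innate immunity had adjusted p = 0.0196 in water and 0.0532 in ascr#10, and the respiratory chain 0.0654 and 0.0040. The difference between the 2 age changes is the same contrast as the interaction tested next. There the respiratory chain was called and innate immunity was not.

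Whether the effect of ascr#10 differed between ages was tested as an interaction within the first collection. The difference passed for 758 genes, with the effect lower at 58 h in 609 and higher in 149. For vitellogenins the effect was lower at 58 h in 4 of 6 (5 over the list alone, median difference -0.36, camera adjusted p = 9.36e-09, and adjusted p = 0.123 with an estimated correlation). For msp genes it was lower in 20 of 33 (23 over the list alone, median -0.54), for other spermatogenic genes in 13 of 32 (15, and 1 higher, over the list alone, median -0.49), and for collagens in 51 of 122 and higher in 2 (58 and 4 over the list alone, median -0.31). Camera gave adjusted p = 3.34e-17, 1.07e-09 and 2.21e-12, and 8.91e-06, 0.000341 and 0.00173 with an estimated correlation. Fatty acid metabolism (6 of 24 lower), ribosomal protein genes (0 of 78) and respiratory chain genes (0 of 27) were called with the preset (adjusted p = 8.6e-05, 0.000588 and 0.000858), with adjusted p = 0.123, 0.546 and 0.0119 with an estimated correlation. Over the list alone, 9 were lower and 1 higher in fatty acid metabolism and 6 lower in the respiratory chain.

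The 2 collections of 58 h, which share no library, were compared directly. The effect of ascr#10 passed for 1289 genes in the first, 454 higher and 835 lower, and for 5067 in the second, 2449 higher and 2618 lower. The effects differed for 1783 genes. Muscle had a lower effect in the second collection in 21 of 21 genes (21 over the list alone, camera adjusted p = 6.13e-24, and 0.00615 with an estimated correlation). So did intestine in 11 of 18 (11, and 1 higher, over the list alone, adjusted p = 2.15e-07 and 0.0175), ascaroside biosynthesis in 7 of 10 (8 over the list alone, 1.68e-06 and 0.00615) and innate immunity in 6 of 20 (6 over the list alone, 1.68e-06 and 0.00615). Vitellogenins had a lower effect in the second in 5 of 6 (6 over the list alone, median difference -0.22, adjusted p = 3.02e-06, and adjusted p = 0.112 with an estimated correlation). Moulting genes had a higher effect in 8 of 29 (11 over the list alone, 0.000373 and 0.01). In all, 21 of 29 lists were called, 10 higher and 11 lower, and 7 with an estimated correlation. Across genes the effects had a Pearson r of 0.0787 and a Spearman rho of 0.179 over all genes, and of 0.307 and 0.126 over the 8003 more abundant genes. As mean differences of log2 CPM, with a prior count of 2, the effects had an absolute correlation of 0.178. Of 100 pairs of label splits within collections, 1 gave as large a value, the real one, and the highest other gave 0.12. Of genes called in both, 72.1% had the same sign over all genes and 65.7% over the more abundant, where 71 were higher in both (108 for independent lists). Leaving out 1 library moved the Pearson r over all genes to between 0.0401, without water replicate 1 of the first collection, and 0.118, without ascr#10 replicate 3 of the second, with 0.0403 without water replicate 1 of the second. Of 699 genes called in both, 431 were lower in both (137 for independent lists), 73 higher in both (69.5 for independent lists) and 195 opposite. The effects at 50 h, which share no library with either, had the same sign in 91.9% of 357 genes called there and in the first collection, and in 58.7% of 601 called there and in the second.

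The placement of exposed worms along the change with age was measured as the slope, across genes, of the ascr#10 effect on the age effect in water. It was 6.64% of the age change in the second collection of 58 h (r = 0.406, 75.5% of genes of the same sign), which shares no library with the age comparison. At 50 h it was 5.35% (r = 0.314) and in the first collection of 58 h 7.36% (r = 0.310). Shared water samples alone gave 0.75% and -1.1% in simulations without an effect, with covariances of 0.019 and -0.027 against 0.134 and 0.184 observed. Other splits of the 6 samples of a set reached at most 2.94% over the 3 sets, and with 10 splits an exact share cannot go below 0.1. In the 8003 more abundant genes the slopes were 11.5%, 3.20% and 8.08%.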

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

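The tests of shared msp reads, of a uniform shift, of dilution in each collection, of matched lists at 58 h and of scaling for ribosomal proteins, and of germline share were chosen after the results they bear on were seen, and the others here before.

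The effect of ascr#10 differed between ages for 758 genes by the interaction test. Of the 4 with the smallest p, oac-14 differed by 0.925 (log2 effect of -0.64 at 50 h and 0.28 at 58 h, first collection), F41F3.3 by -2.672 (-0.41 and -3.08), vit-3 by -0.498 (0.59 and 0.09) and fat-7 by -0.772 (0.78 and 0.01). At 58 h F41F3.3 was at 5.35 CPM in water and 0.63 in ascr#10 in the first collection, and at 0.202 and 0.222 in the second, where it did not pass (log2 effect of 0.14, adjusted p = 0.784). In the second collection the effects were -0.16 for vit-3 and -0.12 for fat-7. Of 100 splits of the samples 2 gave as many genes, the real one included. The other, with 2792 genes, had the labels of 1 age swapped whole, which turns the difference of effects into their sum, and the highest of the rest was 588. Splits that mix the labels take away the effect of exposure itself, and not only its difference between ages. They therefore cannot exclude chance for that difference.

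The effect also differed between the collections of 58 h, for 1783 genes. Y58A7A.3 differed by -0.959 (0.21 in the first and -0.75 in the second), F53B2.8 by -0.876 (0.43 and -0.45), faah-2 by -0.75 (0.46 and -0.29) and oac-14 by -0.885 (0.28 and -0.60). Of 100 splits 4 gave as many genes, the real one included. The highest, 4083, had 1 collection swapped whole, and the highest of the rest was 2311. These splits have the same limit and cannot exclude chance for the difference between collections.

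At 58 h, 100 of the 200 possible splits within collections were drawn. Of these 1 gave as many genes as the real 3548, the real one itself, and the highest other gave 2076. This argues against chance, at a share of 1 in 100 splits. At 50 h and for age, 3 samples against 3 allow 10 splits and no share under 0.1. Only the real split, 1 of 10, gave as many genes (1306, 12789 and 12946), and the highest other gave 0.

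Spermatogenic transcripts were lower in exposed worms at 58 h in both collections, and shared msp reads are argued against as the whole cause by the median of -0.466 in spermatogenic genes other than msp. Dilution by RNA of other germ cells would lower somatic lists alike, yet in the first collection the lowest of the muscle, intestine and pan-neuronal medians was -0.004 (SE 0.018) against -0.585 (SE 0.13) for both sperm lists. In the second, muscle lay at -0.274 (SE 0.036) against -0.43 (SE 0.12), which leaves a part by dilution open, while the intestine list lay at -0.114 (SE 0.024), which argues against dilution as the whole cause. A shift by 1 share of the age change would give equal shares in all genes. The effect was 17% of it in 62 sperm genes (SE over genes 1.7) against 10.5% in 3449 other genes that fell at least 2-fold (SE 0.49) in the first collection, and 13% (SE 1.3) against 10.3% (SE 0.32) in the second. Collagens that fell as far had 14.5% and 1.13%. This argues against 1 equal share as the whole cause, narrowly in the second collection, and genes are not independent replicates. The first collection also shares water samples with the age change. A shift in stage need not give equal shares, since genes may change at different times, so it stays open. Fewer or earlier-spent sperm in exposed worms stays an open hypothesis, not tested here.

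Ribosomal protein transcripts were higher in exposed worms. A uniform shift along the change with age, by 1 share in all genes, is argued against by the list's fall with age (median -0.209). With 2 ages sampled, a shift in stage stays open, since genes may change at different times. Scaling stays open for the rise itself, since the median at 50 h was 0.006 on log2(TPM + 1) against 0.077 with TMM. The median of all genes was lower there too, at -0.059 against -0.002, so the list lay above all genes under both. It also did with RLE size factors (0.070 against -0.010). At 50 h the list lay at percentile 0.01 of random lists matched on length and expression, so that genes of that kind rose as much or more and expression level or length may account for it. At 58 h the percentile was 98.81, which argues against the same account there. Matching was imperfect at both ages, though (median log2 CPM of 8.94 in matched lists and 10.1 in the list). Random lists also drew genes singly, so a list whose genes move together can look extreme.

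The muscle list was lower in exposed worms of the second collection (21 of 21 genes), was not called in the first (adjusted p = 0.929), and differed between them (adjusted p = 0.00615 with an estimated correlation). Depth is argued against, since 20 of 21 muscle genes were called lower after thinning the second collection to 28.2 M counts. A larger germline share of the RNA would lower somatic lists alike, and is argued against as the whole cause by an intestine median of -0.114 (SE 0.024) against -0.274 (SE 0.036) for muscle in that collection. A part by germline share stays open, since the effect on the oocyte list was higher in the second collection in 10 of 26 genes (camera adjusted p = 1.53e-05, and adjusted p = 0.143 with an estimated correlation) and the pan-neuronal list also lay lower there, at -0.173. A difference in stage between collections stays open and goes with the collection.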

How the results depend on the processing

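The counts of genes changed at least 1.5-fold were chosen after the data were seen, and all other alternatives before. Called genes stayed within 1.5 times the reported number with DESeq2 (1339 at 50 h, 4600 at 58 h), RLE size factors (1230, 4423), no low-count filter (1164, 3745), the stricter filter (1254, 4063) and length-scaled counts (1029, 2949). They moved further with limma on log2(TPM + 1) (1988 at 50 h, 1836 at 58 h), with the samples of 50 h alone (2840), with the first collection alone at 58 h (1045), with no batch term (394), for the common 58 h effect minus that at 50 h (1208), and at a 1.5-fold minimum (147 at 50 h, 480 at 58 h). At 50 h, leaving out any 1 sample (741 to 862) and taking the replicate number as a block also moved the number further. The cause of these moves was not tested, apart from the added fold condition. Leaving out each sample gave 741 to 862 genes at 50 h, 2593 to 3882 at 58 h, 12435 to 12517 for age in water, 12598 to 12691 for age in ascr#10, 577 to 732 for the difference between ages and 1448 to 2098 for that between collections.

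Camera with an estimated correlation called 2 lists at 50 h, 3 at 58 h and 11 for age in water, and the first collection alone called 9 at 58 h. The correlation of the collections was 0.307 in the upper 8003 genes by expression, where the rank correlation was 0.126 against 0.179 over all genes. Over all genes it was 0.0787, and ranged from 0.0401 without water replicate 1 of the first collection to 0.118 without ascr#10 replicate 3 of the second, and was 0.0403 without water replicate 1 of the second. Slopes on the age change were 6.46 to 6.83 percent for the second collection and 5.18 to 5.92 percent at 50 h. In the first collection alone hsp-16.2 turned to 0.195 (adjusted p = 0.578) and daf-22 to 0.06 (adjusted p = 0.577), and neither passed there. Of the named genes at 58 h, 28 lost their call in the first collection alone, 35 without a batch term and 4 in the second collection alone (col-146, ced-10, clec-265 and pho-9), in the same direction.

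The replicate numbers did not pair the samples in every set. In the second collection, replicates 1 and 2 correlated with their own number at 0.32 and 0.27, against 0.038 and -0.028 for the best other. Replicate 3 there did not (-0.025 against 0.19). Own-number correlations of deviations ran from -0.2 to 0.068 at 50 h, -0.11 to 0.001 in the first collection of 58 h and -0.025 to 0.32 in the second, and not every sample correlated best with its own number. With the number as a block, 818 genes were called at 50 h, 2659 at 58 h, 791 and 1875 for the differences between ages and collections, 12754 and 12927 for age in water and in ascr#10, and 7 and 15 lists at 50 h and 58 h. Of 44 named genes at 50 h, 6 lost their call under the block (acox-1.3, daf-22, spe-9, daf-28, ins-7 and gcsh-1, adjusted p = 0.0524 to 0.111), as did cosa-1 at 58 h (adjusted p = 0.065). Thinned to the mean depth of the first collection (28.2 M counts per sample), the second still called 3559 genes, against 5067 at full depth and 1289 in the first.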

Other observations

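The proteasome test was fixed before its result was seen, on subunits other than those that drew attention, and the genes named here were chosen after their values were seen.

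Of the 97 genes that passed as lower in exposed worms in each of the 3 exposure comparisons, 4 are given here. icl-1, the isocitrate lyase and malate synthase of the glyoxylate cycle, had log2 effects of -0.51 at 50 h and -0.35 and -0.34 in the 2 collections of 58 h, from 1750 ± 26 to 1230 ± 7.4 CPM at 50 h (SD, n = 3 each). sodh-1, an alcohol dehydrogenase, had effects of -0.47, -0.57 and -0.57, where the ascr#10 stock had been kept in ethanol and the control was water. The zinc transporter gene cdf-2 had effects of -0.42, -0.45 and -0.43, and the noncoding RNA tts-1 -0.47, -0.54 and -0.31. For independent lists 4.65 genes would be lower in all 3. Another 28 were higher in all 3 (3.3 for independent lists). With age in water, 82 of the 97 also passed as lower and 8 as higher, and 20 of the 28 as higher and 5 as lower. A shift along the change with age stays open for these genes as a group. The 4 named genes changed with age by -0.50 (icl-1), -0.54 (sodh-1), -0.86 (cdf-2) and 0.05 (tts-1). Slopes of 5.35% to 7.36% on the age change would not give effects of their size. A single gene need not follow a slope across genes, though, and these 4 were picked after their values were seen. In water worms of 58 h icl-1 was at 1240 CPM in the first collection and 431 in the second, and sodh-1 at 120 and 39.4. Levels of these 2 genes thus also differed between collections without ascr#10. Over all 16006 genes 6783 were lower and 6006 higher with age. The first collection and 50 h share water samples with that comparison, while the second shares none, and of its 2618 lower genes 2032 were lower with age and of its 2449 higher genes 2063 were higher. The second collection shares no library with the other comparisons, nor does the comparison at 50 h with that of the first collection at 58 h.

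Among the 28 were the proteasome subunits pas-2 (0.11, 0.10 and 0.11), pas-3 (0.10, 0.09 and 0.09) and pas-7 (0.11, 0.11 and 0.10), and smo-1 and ubc-9, which encode SUMO and its conjugating enzyme. The mean of the 3 effects had a median of 0.093 over the other 30 subunits, at percentile 100 of matched random lists (0.04 to 0.07). These subunits were measured in the same samples as the 3 that drew attention, and random lists drew genes singly. A list whose genes move together can then look extreme, so the percentile is not independent support. By comparison the medians of the 30 subunits were 0.087 at 50 h, 0.04 in the first collection and 0.147 in the second, with 15, 2 and 29 of 30 higher and 0 lower. A rise of the proteasome as a group is a hypothesis consistent with this, resting on few called subunits in the first collection, and a shift along the change with age stays open, since 29 of 30 also rose with age in water and 1 fell.

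F59B2.12 had 91 to 105 counts per sample in water worms of the first collection at 58 h, 7 to 23 in ascr#10 worms of 50 h, and 0 to 1 in each of the other 12 samples.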
